A study of Mus musculus with 6 samples.

How the data were processed

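The series measured messenger RNA in 6 libraries of mouse induced pluripotent stem cells (iPSC), cells returned to an embryonic-like state from fibroblasts with the factors Oct4, Sox2, Klf4 and Myc (OSKM). Per the labels, 3 libraries came from clones of AICDA knockout (KO) fibroblasts and 3 from clones of wild-type (WT) fibroblasts. All were at passage 4 in serum with leukaemia inhibitory factor (LIF), with RNA from a Qiagen RNeasy kit. Libraries were made with the Illumina TruSeq RNA version 2 kit, per the labels, which does not mark strand, so reads of overlapping or antisense genes cannot be told apart.

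The authors deposited 1 table for the whole series. It held raw read counts per gene and library, whole numbers with a different total in each library. STAR 2.3.0e, HTSeq 0.6.0 and the mouse build mm10 are named in the submitters' processing notes, with no settings and no annotation release. The same deposited table held a normalised signal, the count divided by 1 size factor per library, and its mean over the libraries. The size factors recovered from it ran from 0.768 to 1.45. It also held the authors' log2 fold change of AICDA KO over WT with its standard error, their test statistic, a score equal to the fold change over its error, and their p-value with its adjusted form. These come from DESeq2 per the file headers and name, with the version not given in the sources used here. The authors' log2 fold change of Aicda was 5.72, against 6.74 here, and their values were used only for comparison.

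The table had 24725 lines for 22753 Ensembl genes, because a gene stood once per human ortholog, and the 1972 repeats, which held identical values, were removed. In 27 lines a spreadsheet had turned the symbol into a date, and the symbol was restored from the gene identifier. Of the genes, 22740 were protein-coding, and long non-coding genes such as Xist, H19 and Meg3, together with Klf4, were not analysed here. Coordinates are those of the table, in mm10, counted from 1. Exon overlap of the 132 named genes with other genes was checked against GENCODE M21, which is on the same build. For 8 of them at least 20% of the exon bases were shared with another gene.

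Library totals ran from 24116402 to 44327173 counts. Counts were tested with edgeR 4.0.16 in R 4.3.3 after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with the robust quasi-likelihood F-test of genotype alone and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Levels are in CPM, read counts scaled to library size in the usual way, here with the TMM factors, and means are given with the SD over 3 libraries. Log2 fold changes are given with a standard error (SE) worked back from the test. It is the size of the log2 fold change over the square root of the F statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, over 23 lists with at least 3 measured members.

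Design, lists, alternatives and naming rule were fixed before the data were examined. Named were Aicda, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 1 CPM, the 5 genes of smallest p in each direction, up to 4 members of smallest p per list, and the OSKM factors with Nanog. Predicted gene models were not named. The rule gave 111 genes, and another 21 were named after their values were seen, as said where they appear. A further 4 gene lists were also written after the values were seen.

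The fit was tested on simulated counts with the means and library sizes of the comparison of AICDA KO with WT, over 14683 genes. It called 10% of 50 genes changed 1.25-fold, 56% of 50 changed 1.5-fold, 86% of 50 changed 2-fold and 100% of 50 changed 4-fold. It called 14 of 14463 unchanged genes and none of the 200 changed genes in the wrong direction, 0 in the simulated count. Camera called a simulated list of 20 genes raised 1.5-fold and 0 of 22 unchanged lists. The simulated genes varied independently, and in other splits of the real libraries, whose genes are correlated, camera called up to 4 lists. Each simulated gene had the same spread in both groups. The real biological coefficients of variation were 16.6% in the libraries labelled AICDA KO and 5.1% in WT. The simulation also changed few genes, where 33.7% of the real genes were called, so its shares need not hold for the real libraries.

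Alternatives were a replicate block, the Wald test of DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter of at least 5 CPM in 3 libraries, each library left out, a 2-fold minimum, autosomal genes alone, and no fibroblast, haematopoietic or endothelial list genes. After seeing the data, limma-voom with a separate variance per genotype, counts thinned to equal depth, and a run without chromosome 6 from 120 Mb on were added. Pseudocount alternatives were written for normalised values and had no use with counts. Chromosome medians used genes averaging at least 8 CPM. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Counts of genes with near-identical copies, such as Tuba3b, the Usp17l, Zscan4, Rhox and Xlr families and Hspa1a, are uncertain. Intervals on counts cover counting error only.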

Results

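RNA levels were measured in 6 libraries of mouse iPSC clones, 3 labelled AICDA KO and 3 labelled WT, to compare reprogrammed cells with and without the gene for activation-induced cytidine deaminase, an enzyme that deaminates cytosine in DNA. The libraries labelled AICDA KO held 25939352, 24116402 and 32091490 counts in replicates 1, 2 and 3, and the WT libraries 44327173, 32684320 and 30998684. Between 17021 and 17795 genes had at least 1 read. The labels say no more than that the libraries are clones, so p-values measure the spread between these samples, whatever its source. Whether the clones of a label came from separate animals or lines is not given. A difference between the labels therefore cannot be told apart from one between animals or lines. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.7 to 34.7 between the libraries labelled AICDA KO and 4.64 to 9.74 between the WT libraries. The biological coefficient of variation was 16.6% in the libraries labelled AICDA KO and 5.1% in the WT libraries.

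Aicda (ENSMUSG00000040627, chromosome 6, 122553801 to 122564180), the gene named as knocked out, was abundant in the libraries labelled AICDA KO, against the labels. It was near the floor in WT. The gene may be near zero in wild-type iPSC, so the low WT level alone does not go against the labels. The libraries labelled AICDA KO held 679, 924 and 922 Aicda reads, and the WT libraries 12, 10 and 10. The level was 31.6 ± 6.40 CPM (SD, n = 3) against 0.295 ± 0.0247 CPM (SD, n = 3) in WT. The log2 fold change was 6.74 ± 0.22 (SE), with an adjusted p of 1.705e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The two-sided exact permutation test of the 6 levels gave p = 0.1, the smallest that 3 against 3 can give. The deleted part of the gene is not given in the labels, so a count over the whole gene cannot show whether it is missing. The groups are therefore called by their labels throughout, and every direction given is that of the libraries labelled AICDA KO relative to the libraries labelled WT.

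**Figure D1:**
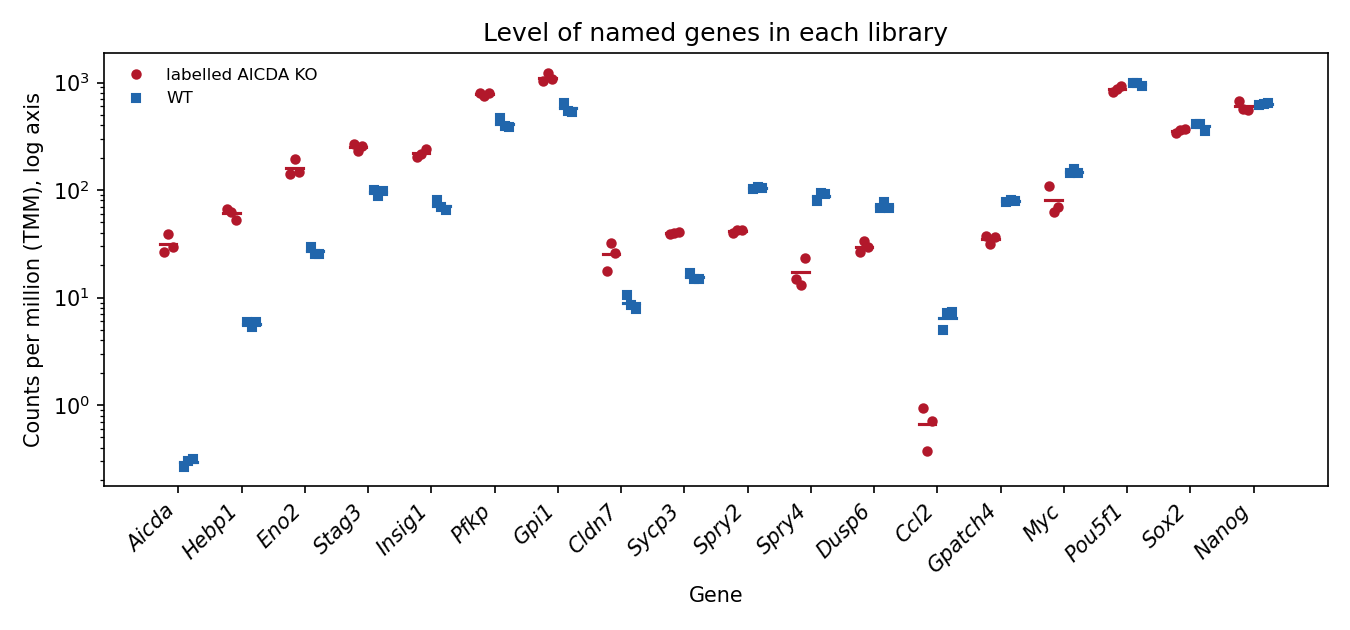
Level of 18 named genes in each library, in TMM-scaled CPM on a log axis. Points are libraries (circles labelled AICDA KO, squares WT) and bars are group means. Aicda lay between 26.5 and 38.8 CPM in the libraries labelled AICDA KO and between 0.268 and 0.317 CPM in WT, while Pou5f1, Sox2 and Nanog overlapped between the groups.

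Between the libraries labelled AICDA KO and WT, the lists of glycolysis, epithelial and germline genes were called higher by camera with its preset correlation, and Spry2, Spry4 and Dusp6 fell, while Pou5f1, Sox2 and Nanog did not pass the test. Each of these 3 list calls was lost at an adjusted p = 0.518 with an estimated correlation. Among the genes with the smallest p, Hebp1, a haem-binding protein gene, stood at 60.7 ± 7.08 CPM against 5.74 ± 0.345 CPM in WT (SD, n = 3 each). Eno2, an enolase of glycolysis, stood at 160 ± 28.6 CPM against 26.9 ± 2.45 CPM, Stag3, a cohesin subunit of meiosis, at 251 ± 19.4 against 95.7 ± 5.96 CPM, and Insig1, a regulator of sterol synthesis, at 220 ± 18.3 against 71.7 ± 7.87 CPM (SD, n = 3 each). Their log2 fold changes were 3.40 ± 0.11, 2.57 ± 0.13, 1.39 ± 0.08 and 1.62 ± 0.09 (SE). Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 105 ± 2.08 CPM in WT to 41.5 ± 1.40 CPM (SD, n = 3 each), a log2 fold change of -1.34 ± 0.06 (SE). The adjusted p of these 5 genes lay between 1.705e-06 and 7.701e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Klhdc4, Gpatch4, Zc3h4 and Ide, the insulin-degrading enzyme gene, were the other falls of smallest p, with log2 fold changes of -0.96, -1.17, -1.16 and -0.81.

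Of 14805 genes tested, 4990 (33.7%) changed, 2577 higher and 2413 lower in the libraries labelled AICDA KO. At least a 2-fold change was seen in 336 of those higher and 460 of those lower. The 3 libraries of one label all lay above the 3 of the other for 7446 genes (50.3%), where chance gives 10%. The first principal component held 59.3% of the variance and separated the labels, and the next held 18.8% and set AICDA KO replicate 1 apart. Leaving out WT replicate 1, 2 or 3 lowered the count to 3196, 2329 or 2957. The authors' deposited table called 5849 genes at an adjusted p under 0.05, 3055 higher and 2794 lower, and 4954 genes were called both there and here, all 4954 in the same direction.

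The largest rises after Aicda were in Mal, Hebp1, Myl3, Pkhd1l1, Clec2i, Tuba3b, Usp26, Eno2 and Ccdc172, with log2 fold changes from 5.50 to 2.55. Mal stood at 15.6 CPM in replicate 2 of the libraries labelled AICDA KO, at 0.39 and 0.93 CPM in replicates 1 and 3, and at 0.112 to 0.127 CPM in WT. Its edgeR adjusted p of 0.0466 was lost in 7 alternatives (0.0767 to 0.179), among them without AICDA KO replicate 3 (0.0767) and without WT replicate 1 (0.131), 2 (0.152) or 3 (0.103). By edgeR the call of Myl3 was lost without WT replicate 1 (adjusted p 0.0525) or 3 (0.0508), and that of Ccdc172 without WT replicate 2 (0.0758) or 3 (0.0648). Hebp1 lies on chromosome 6 at 135137519 to 135168215, Clec2i at 128887588 to 128898167, Eno2 at 124760053 to 124769673 and Tuba3b at 145615757 to 145621479. Usp26 lies on chromosome X at 51753959 to 51801233. The largest falls were in Art4, Ccl2, Pirt, Gnat1, Hfe, Tlr5, Spry4, Slc26a9, Shisa6 and Ccdc116. Art4 (chromosome 6, 136848451 to 136857733) had 1 read over the libraries labelled AICDA KO and 125 over the WT libraries, a ratio of 92 (95% exact binomial interval 16.2 to 3661). Ccl2, a chemokine gene (chromosome 11, 82035571 to 82037453), stood at 0.673 ± 0.280 CPM against 6.49 ± 1.33 CPM in WT (SD, n = 3 each), and Hfe, an iron regulator gene, at 0.504 ± 0.235 against 2.84 ± 0.176 CPM (SD, n = 3 each).

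Most genes of glycolysis and the response to low oxygen rose in the libraries labelled AICDA KO. Of 33 measured members 25 rose, 1 fell and 7 did not pass, with the same 25 and 1 when adjusted over the list alone, and the median log2 fold change was 0.61. Gpi1 and Pfkp, enzymes of upper glycolysis, stood at 1112 ± 108 CPM against 574 ± 58.1 and at 783 ± 29.6 CPM against 415 ± 43.8 (SD, n = 3 each), log2 fold changes of 0.96 ± 0.09 and 0.91 ± 0.08 (SE). The glucose transporter gene Slc2a3 (chromosome 6, 122727809 to 122801640), a close neighbour of Aicda, had a log2 fold change of 0.77 ± 0.08 (SE). The mean of the list exceeded the WT mean by 0.64, 0.88 and 0.64 log2 units in replicates 1, 2 and 3. Members outside the end of chromosome 6, from 120 Mb on, numbered 28, of which 21 rose and 1 fell. Camera gave an adjusted p of 5.359e-09, and an adjusted p = 0.518 with an estimated correlation.

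Most epithelial genes rose, and the mean of the list was lowest in AICDA KO replicate 1 among the libraries labelled AICDA KO. Of 20 measured members 13 rose, 0 fell and 7 did not pass (14 and 1 when adjusted over the list alone), at a median log2 fold change of 0.82. Ocln, a tight junction gene, stood at 14.0 ± 0.912 CPM against 5.86 ± 0.664 CPM in WT (SD, n = 3 each). The tight junction gene Cldn7, the desmosome gene Pkp2 and the transcription factor gene Grhl2 had log2 fold changes of 1.49 ± 0.22, 1.18 ± 0.16 and 0.50 ± 0.08 (SE). The list mean exceeded that of WT by 0.31 in replicate 1, 1.19 in replicate 2 and 0.85 in replicate 3. The mean of the trophoblast list, which camera did not call, ranked the libraries alike, at -0.27, 0.73 and 0.48. Krt18, a keratin gene also on the trophoblast list, stood at 23.9, 144 and 80.4 CPM against 24.2 ± 0.964 CPM in WT (SD, 3 libraries), with an edgeR adjusted p of 0.054 that became 0.00289 without AICDA KO replicate 1. Camera gave the epithelial list an adjusted p of 0.0001449, and an adjusted p = 0.518 with an estimated correlation.

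Many germline genes also rose, and the mean of the list was highest in AICDA KO replicate 1. Of 38 measured members 19 rose, 2 fell and 17 did not pass (21 and 2 when adjusted over the list alone), at a median log2 fold change of 0.69. Sycp3, of the synaptonemal complex, stood at 40.0 ± 0.633 CPM against 15.4 ± 1.14 CPM in WT (SD, n = 3 each), though 52.2% of its exon bases are shared with Chpt1 on the opposite strand. Mael and Ddx4, genes of germ cell RNA handling, had log2 fold changes of 1.01 ± 0.10 and 0.74 ± 0.08 (SE). Tuba3b, whose reads can be shared with near-identical copies, had 2.90 ± 0.34 (SE). The list mean exceeded that of WT by 1.13, 0.31 and 0.40 in replicates 1, 2 and 3. The 28 autosomal members gave 17 rises and 2 falls, with means of 1.24, 0.45 and 0.73. The 10 members on chromosome X gave 2 rises and 0 falls, with means of 0.84, -0.08 and -0.51, and the difference between these parts was not tested. Camera gave the list an adjusted p of 0.0008674, and an adjusted p = 0.518 with an estimated correlation.

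**Figure D2:**
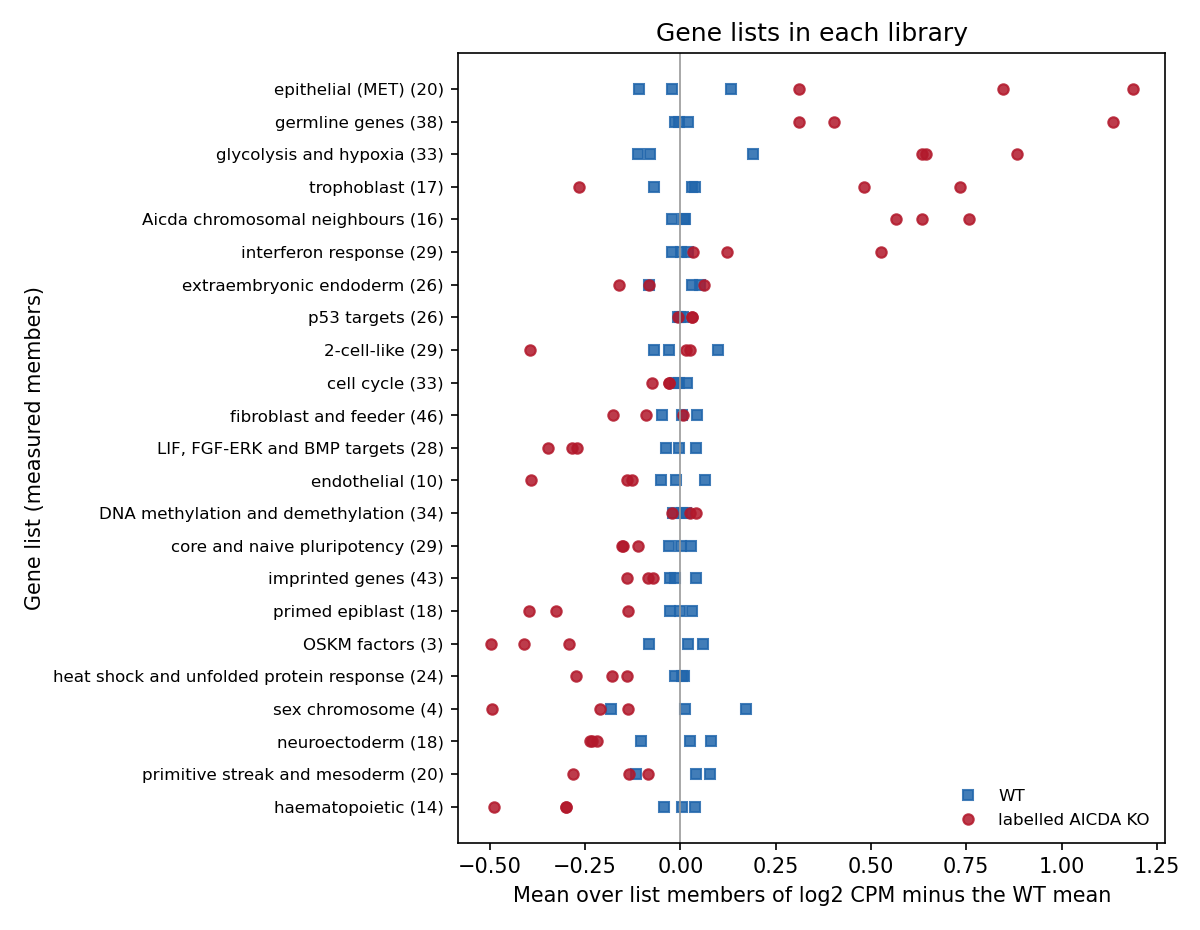
Mean over the measured members of each of 23 gene lists of log2 CPM minus the WT mean, per library (circles labelled AICDA KO, squares WT), lists ordered by median log2 fold change. Glycolysis and hypoxia lay at 0.64, 0.88 and 0.64 in the libraries labelled AICDA KO. Between these libraries the trophoblast list ran from -0.27 to 0.73, the epithelial list from 0.31 to 1.19 and the germline list from 0.31 to 1.13.

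The pluripotency factors Pou5f1 (876 ± 52.7 CPM against 967 ± 35.5), Sox2 (356 ± 13.9 against 392 ± 34.7) and Nanog (600 ± 70.0 against 628 ± 14.2; SD, n = 3 each) gave edgeR adjusted p values of 0.127, 0.185 and 0.571. Without AICDA KO replicate 3, Pou5f1 passed as lower, at an edgeR adjusted p of 0.0359. Myc, measured without regard to the origin of its reads, fell with a log2 fold change of -0.88 ± 0.20 (SE) and an edgeR adjusted p of 0.0152, lost without AICDA KO replicate 3 (0.0554) or WT replicate 2 (0.0602). Of the 3 measured OSKM genes, Myc alone was called, also when adjusted over the list alone (camera adjusted p = 0.33). Of 29 core and naive pluripotency genes 5 rose and 8 fell (5 and 9 when adjusted over the list alone; camera adjusted p = 0.393). Dppa5a and Dppa3, markers of naive cells, had log2 fold changes of 0.58 ± 0.06 and 1.51 ± 0.21, and Zic3 and Gbx2 of -0.92 ± 0.08 and -1.16 ± 0.13 (SE). Dppa3 is a close neighbour of Aicda on chromosome 6 (start 122626410). Of 18 primed epiblast genes 2 rose and 7 fell, as when adjusted over the list alone (camera adjusted p = 0.212), the falls including Foxd3, Fgf15, Pou3f1 and the DNA methyltransferase gene Dnmt3b, with log2 fold changes of -1.68, -1.05, -0.98 and -0.66. Exon bases of Gbx2 (43.5%) and Fgf15 (24.9%) are shared with genes on the opposite strand.

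Spry2, Spry4 and Dusp6, feedback genes of growth factor signalling, fell, while camera did not call the list that holds them. Of 28 targets of LIF, FGF-ERK and BMP signalling 5 rose and 10 fell (5 and 11 when adjusted over the list alone; camera adjusted p = 0.212). Spry4 (chromosome 18, 38586268 to 38601268) stood at 17.1 ± 5.30 CPM against 88.6 ± 8.31 CPM in WT, and Dusp6, an ERK phosphatase gene, at 29.9 ± 3.38 against 71.7 ± 5.15 CPM (SD, n = 3 each). Their log2 fold changes were -2.36 ± 0.20 and -1.26 ± 0.10, and that of Id3, a BMP target, was -1.14 ± 0.13 (SE). Of 24 heat shock and unfolded protein genes 3 rose and 11 fell, as when adjusted over the list alone (camera adjusted p = 0.0691), with the chaperone genes Hspa8 at -0.85, Dnajb1 at -0.58 and Hspb1 at -0.54, and Asns, for asparagine synthetase, at 0.62. Of 33 cell cycle genes 5 rose and 9 fell, as when adjusted over the list alone (camera adjusted p = 0.776), with Ccnd1, which shares 23.4% of its exon bases with a gene on the opposite strand, at -0.94 and the inhibitor gene Cdkn1b at 1.01. Cdkn1b lies toward the end of chromosome 6, beyond Aicda (start 134920401). Of 26 p53 targets 5 rose and 4 fell (7 and 4 when adjusted over the list alone; camera adjusted p = 0.833), with Sesn2 at -0.76 and Trp53inp1 at 0.50. Of 29 interferon response genes 6 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.585), with the transcription factor gene Stat2 at 0.83 and the RNA sensor gene Ddx58 at -1.02.

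Genes of DNA methylation and demethylation went both ways. Of 34 measured members 7 rose and 8 fell, as when adjusted over the list alone (camera adjusted p = 0.776). The list's median of -0.08 and its mean of 0.02 differed in sign. The deaminase gene Apobec3 stood at 267 ± 2.49 CPM against 187 ± 9.42 CPM in WT, Gadd45b at 77.3 ± 6.63 against 34.2 ± 7.23 CPM, and Zfp57, a keeper of imprints, at 428 ± 6.98 against 627 ± 46.8 CPM (SD, n = 3 each). Of 43 imprinted genes 6 rose and 9 fell, as when adjusted over the list alone (camera adjusted p = 0.585). Slc38a4 and Copg2 had log2 fold changes of 1.13 ± 0.10 and 0.51 ± 0.07, and Zdbf2 and Tssc4 of -1.63 ± 0.20 and -0.49 ± 0.08 (SE).

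Camera called none of the lists of other cell types, though each had members called in both directions. Of 46 fibroblast and feeder genes 9 rose and 13 fell (11 and 14 when adjusted over the list alone; camera adjusted p = 0.517), with Serpine1, Lox and Col12a1 at log2 fold changes of 0.93, 0.97 and 1.05 and Timp2 at -0.98. Of 26 extraembryonic endoderm genes 4 rose and 7 fell, as when adjusted over the list alone (camera adjusted p = 0.776), where the median of 0.09 differed in sign from the direction of the test, and Fst and Sox7 stood at -1.22 and -1.32. Of 20 primitive streak and mesoderm genes 2 rose and 4 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.393). The mesoderm genes Wnt3 (1.17), Gata4 (-0.65) and Bmp4 (-0.85) were called by edgeR at adjusted p values of 0.0295, 0.0395 and 0.0441, and lost the call when any 1 WT library was left out (0.0779 to 0.145). Wnt3 also lost it without AICDA KO replicate 2 (edgeR adjusted p 0.0776) or 3 (0.0691), and Bmp4 without AICDA KO replicate 3 (0.0661). Of 18 neuroectoderm genes 3 rose and 4 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.337), with Sox1 at -1.92 ± 0.22 (SE) and Dll1, which shares 20.5% of its exon bases with a gene on the opposite strand, at 2.03 ± 0.185 (SE). Of 17 trophoblast genes 2 rose and 1 fell (1 and 1 when adjusted over the list alone; camera adjusted p = 0.393), and their mean lay below WT in AICDA KO replicate 1 (-0.27) and above it in replicates 2 (0.73) and 3 (0.48). Gata2, a trophoblast transcription factor gene, stood at 17.0 ± 6.10 CPM against 5.32 ± 1.18 CPM in WT (SD, n = 3 each). Of 29 genes of 2-cell-like cells 1 rose and 6 fell (1 and 5 when adjusted over the list alone; camera adjusted p = 0.748), where the median of 0.003 and the mean of -0.09 differed in sign, with Tmem92 at -0.93 and Rnf213 at 1.68. Of 14 haematopoietic genes 2 rose and 4 fell (2 and 5 when adjusted over the list alone; camera adjusted p = 0.393), and of 10 endothelial genes 2 rose and 3 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.585). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0.8 to 3.1 CPM in all 6 libraries and 0 of the 4 passed (0 also when adjusted over the list alone; camera adjusted p = 0.393). Camera called 3 of the 23 lists, 0 with an estimated correlation, and fry called 10 by direction and 22 for change in either direction.

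Large changes were frequent toward the end of chromosome 6, where Aicda lies, and most so beyond Aicda. Of 16 measured neighbours, Aicda included, 8 rose and 1 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0503), among them Dppa3, Foxj2, Necap1 and Slc2a3, with log2 fold changes of 1.51, 1.03, 0.53 and 0.77. The share called was 56.2% against 33.7% elsewhere (odds ratio 2.53, two-sided Fisher's exact test, p = 0.0661), and without Aicda 8 of 15 were called (odds ratio 2.25, p = 0.168 by the same exact test). With all 16, the exact p was 0.00136 to 0.0404 when any 1 library other than AICDA KO replicate 1 was left out, and 0.0661 without that library. Over the wider end of the chromosome from 120 Mb on, a boundary set after seeing the data, 31 of 190 tested genes (16.3%) were called with at least a 2-fold change, 17 higher and 14 lower, against 5.23% elsewhere. The window from 130 to 140 Mb ranked 1 of 221 windows of 10 Mb in this share, at 37.1% of 35 genes. The window from 120 to 130 Mb, which holds Aicda, ranked 8, at 12% of 108 genes, and that from 140 to 150 Mb ranked 16, at 10.6% of 47 genes. The median log2 fold change of the 190 genes was 0.02.

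**Figure D3:**
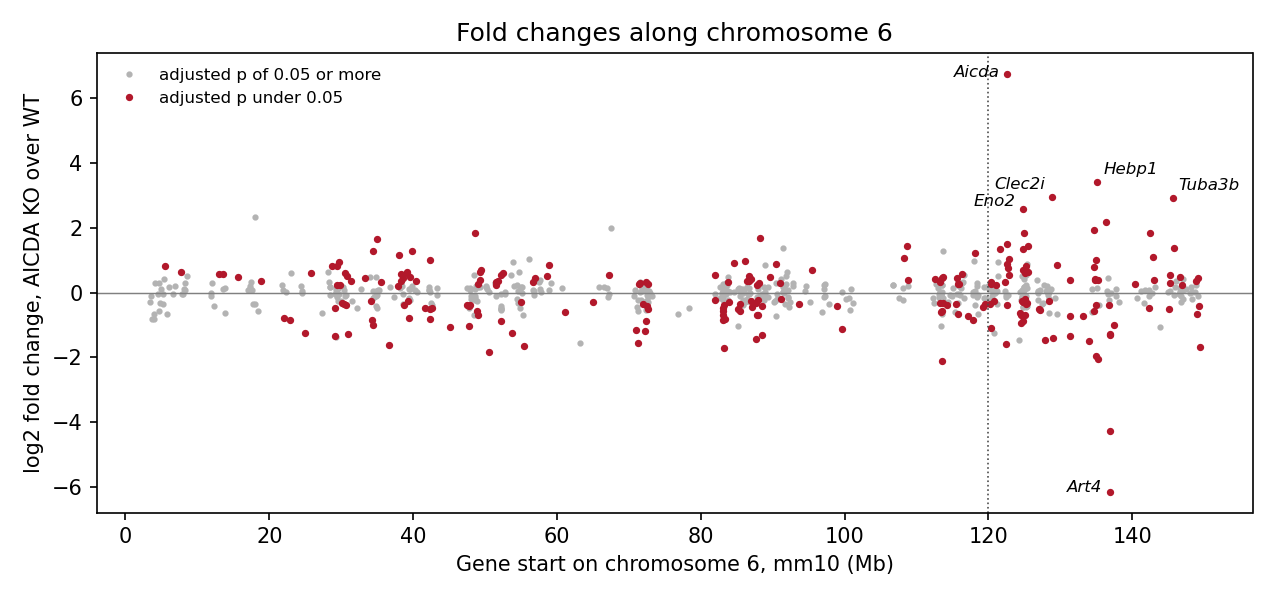
log2 fold change of libraries labelled AICDA KO over WT for the 701 tested genes of chromosome 6, by gene start in mm10 (Mb). Red points had an adjusted p under 0.05 and grey points did not, and the dotted line stands at 120 Mb. Aicda, at 6.74, and Art4 mark the extremes, and 31 of 190 genes right of the line were called with at least a 2-fold change.

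On chromosome X the library of AICDA KO replicate 3 stood apart along part of its length. Against the mean of replicates 1 and 2, its median log2 difference was -0.07 over 133 genes up to Nsdhl (start 72918557) and -0.93 over 211 genes from Zfp185 (start 72987339) on, where 99.1% of genes were lower. Against the WT mean, the 211 genes had medians of 0.20, 0.18 and -0.695 in replicates 1, 2 and 3, and the 133 genes 0.19, 0.15 and 0.15. Of all X-linked genes tested 20.3% were called against 34.2% on autosomes. The share was 39.1% before this position and 9.6% after it. After it, replicate 3 lay apart from replicates 1 and 2, which adds to the spread within their group. The lower share therefore does not show that fewer of these genes differ between the labels.

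**Figure D4:**
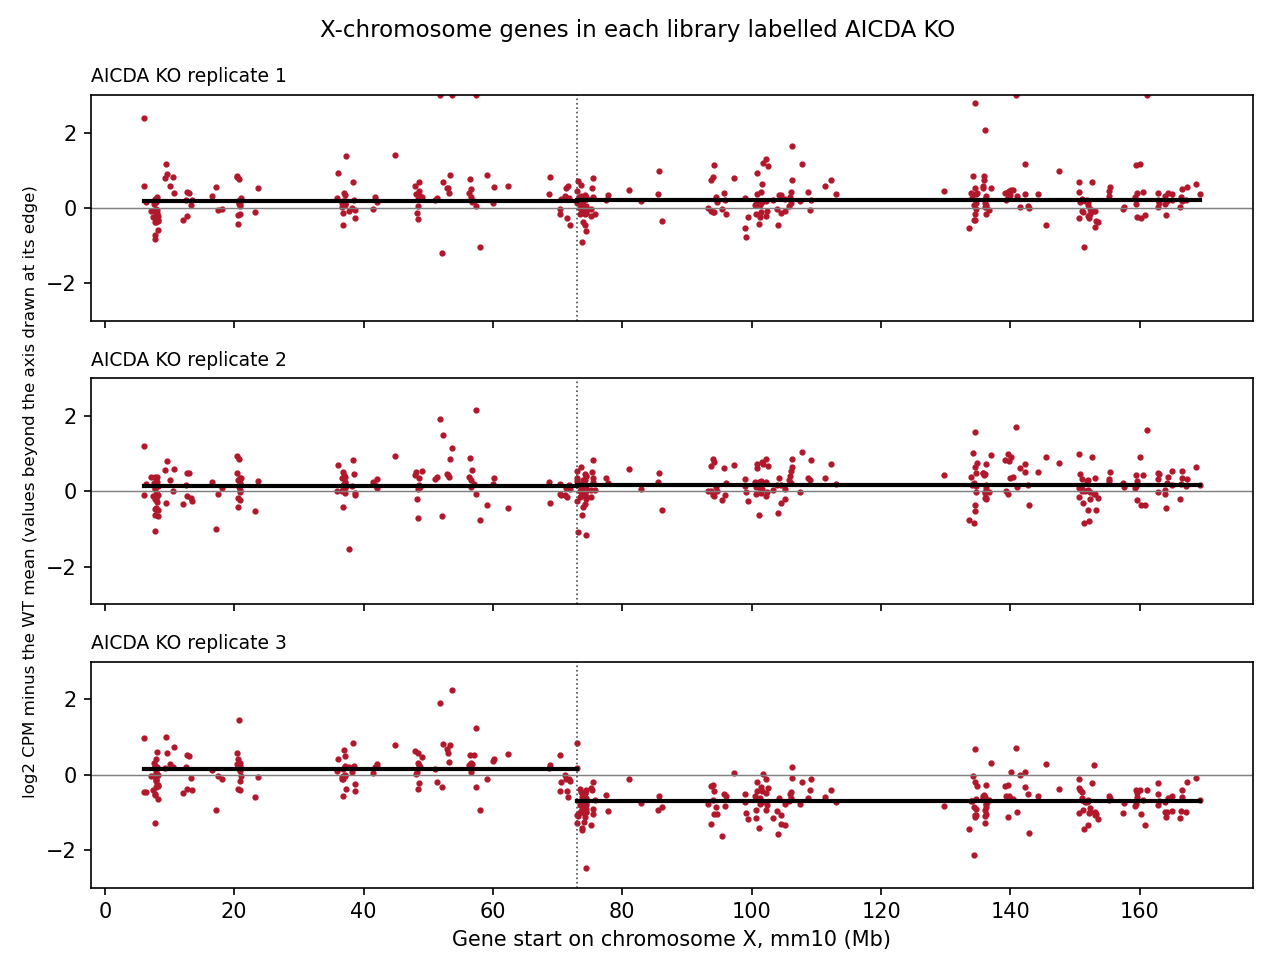
log2 CPM minus the WT mean of 344 X-linked genes averaging at least 8 CPM, by gene start in mm10 (Mb), in each library labelled AICDA KO. Points are genes, black bars are medians before and after the dotted line at 72987339, and 5 values beyond the axis are drawn at its edge. The median after the line was -0.695 in replicate 3 and 0.20 and 0.18 in replicates 1 and 2.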

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

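Of the alternatives, 3 were chosen after seeing the data: limma-voom with a separate variance per genotype, thinning to equal depth, and leaving out chromosome 6 from 120 Mb on. The 4990 genes changed, 2577 higher and 2413 lower, stayed within 1.5 times of these counts in 15 of 19 alternatives. No gene called in both turned direction (0 opposite signs). With a 2-fold minimum 796 changed, 336 higher and 460 lower, by the construction of that threshold. Leaving out each library gave 2329 to 5593 changed, 1175 to 2897 higher and 1154 to 2720 lower, the low values each without a WT library (3196, 2329 and 2957 without replicates 1, 2 and 3, of which 3163, 2319 and 2921 were among the 4990). The cause was not tested. Upper-quartile scaling gave 2113 higher and 2863 lower, with a median of all genes of -0.039 in place of 0.008. With the replicate number as a block 3619 genes changed and 3 lists were called. Same-numbered libraries had correlations of -0.107, 0.002 and -0.145 after removing group means. No pairing by number was seen, though 3 such values cannot exclude one.

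The Aicda fold change held in all 15 alternatives, between 6.56 and 6.85. In place of 3 lists, camera called 6 with DESeq2, 5 with limma-voom, 5 with a separate variance per genotype, 6 with the stricter filter and 0 with an estimated correlation, fry called 10, and leaving out each library gave 3 to 4. The cause was not tested. The glycolysis, epithelial and germline lists passed in 17 of 18 alternatives each. Of these, 1 was fry, which compares a list with no change and not with other genes. The others kept camera's preset correlation of 0.01, so they do not test that setting. The estimated correlations of the 3 lists were 0.448, 0.519 and 0.307, and with an estimated correlation camera lost all 3 calls (adjusted p = 0.518). Of 357 pairs of another list and an alternative, 22 passed in the same direction and 8 turned direction, 0 of them called. The odds ratio of the Aicda neighbours, Aicda itself included, was 2.53. Without Aicda it was 2.25 (p = 0.168 by Fisher's exact test), and the alternatives were run only with Aicda included. With Aicda, it passed Fisher's exact test with the replicate block (3.98), limma-voom (3.26), upper-quartile scaling (3.30), a separate variance per genotype (3.27) and thinning (3.13). It ran from 2.81 to 5.44 when each library was left out (p over the alternatives 0.00136 to 0.113 by the same test). The cause was not tested. Over 2065 pairs of a named gene and an alternative, 78 calls were lost, 4 were gained and 1 reversed, Kdm5d, from -0.31 to 0.12 without WT replicate 3 (range -0.55 to 0.12), never called. Alternatives for pseudocounts were not run, since counts were used. Depth and spread limit calls of small changes. In the simulation, whose limits are given above, 56% of 1.5-fold changes were called.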

Other observations

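Except for the counts over splits of the libraries, the tests and gene lists of this part, and the genes not named before it, were chosen after the result was seen, so the lists are no independent evidence. Most of the measured sterol and lipid synthesis genes were higher in the libraries labelled AICDA KO. Of 31 measured, 22 rose and 2 fell, at a median log2 fold change of 0.70 (camera p = 1.584e-08, p = 0.204 with an estimated correlation). Besides Insig1, the sterol carrier gene Stard4, Hmgcr, of the rate-limiting step of cholesterol synthesis, Sqle and the receptor gene Ldlr had log2 fold changes of 1.22 ± 0.08, 1.12 ± 0.13, 1.03 ± 0.10 and 0.93 ± 0.10 (SE). Fasn and Ebp were the falls, at -0.20 and -0.23, and their edgeR calls were each lost in 6 alternatives (adjusted p 0.0674 to 0.156 and 0.0792 to 0.143), among them without any 1 WT library or without AICDA KO replicate 1. Fasn also lost its call without AICDA KO replicate 2 (edgeR adjusted p 0.0743) and Ebp without replicate 3 (0.0792). The list mean exceeded that of WT by 0.46, 0.58 and 0.84 in replicates 1, 2 and 3.

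Targets and feedback genes of ERK fell more often than they rose. Of 19 measured, 10 fell and 1 rose, at a median of -0.41 (camera p = 0.0001607, p = 0.0445 with an estimated correlation, 0.0891 adjusted over these 4 lists). The falls included Phlda1, which shares 33.0% of its exon bases with a gene on the opposite strand, at -1.38 ± 0.13 and Egr1 at -1.20 ± 0.16 (SE), and Spry1, which shares 24.4% in the same way, was the rise, at 0.31 ± 0.10 (SE). The edgeR call of Spry1 was lost in 8 alternatives (adjusted p 0.05004 to 0.135), among them without any 1 WT library or without AICDA KO replicate 1 or 2. Of 40 genes of ribosome biogenesis 24 fell and 0 rose, at a median of -0.25 (camera p = 1.711e-05, p = 0.349 with an estimated correlation), with Nop2 at -0.68 ± 0.09, Bop1 at -0.57 ± 0.08 and Ncl at -0.26 ± 0.07 (SE), the call of Ncl being lost in 3 alternatives, among them without WT replicate 2 (adjusted p 0.0663 by edgeR) or 3 (0.0728). Nop2 lies toward the end of chromosome 6, beyond Aicda (start 125131883). Of 26 genes associated with FoxO factors 15 rose and 3 fell, at a median of 0.42 (camera p = 0.0002605, p = 0.0249 with an estimated correlation, 0.0891 adjusted over these 4 lists). Pik3ip1, an inhibitor of PI3-kinase, stood at 23.8 CPM against 5.61 in WT, and Txnip, Crebrf and Trib2 had log2 fold changes of 0.97, 1.14 and -0.65.

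Of the 10 splits of the 6 libraries into 3 and 3, 1, that by label, called as many as 4990 genes. By edgeR the other splits called 0 at most, with at most 459 genes at an unadjusted p under 0.05, at most 0 by limma-voom and 3 by DESeq2. Each other split puts libraries of both labels on each side. The difference between the labels then adds to the spread within its groups, so these splits could hardly call many genes. For gene lists 8 of the 10 splits, the real one included, called as many as 3 lists by camera with its preset correlation, and the highest other called 4. In both cases 10 splits are too few for a share under 0.05.

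Aicda stood 83.4 times higher in the lowest library labelled AICDA KO than in the highest WT library. This argues against 1 or 2 wrong labels, which would leave a library at the level of the other group. The related gene Apobec1 as the source of the Aicda reads is argued against by its log2 fold change of 0.868, far below the 6.74 of Aicda. Reads passing the other way, from Aicda to Apobec1, were not tested. An exchange of the labels of all libraries cannot be told apart from a transcript of the altered allele, because the deleted part is not given and the WT libraries still held 32 Aicda reads. A promoter within the altered allele may drive the remaining exons, a hypothesis that was not tested.

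Large changes toward the end of chromosome 6, such as Hebp1, Art4, Vwf (1.45), Mansc1 (1.91), Etv6 (-1.50) and Gsg1 (-2.06), were most frequent from 130 to 140 Mb, beyond Aicda. With the large changes placed at random over the tested genes, no 10 Mb window of the genome with at least 20 tested genes reached the 37.1% of this window (35% at most, permutation p = 1e-04, the smallest they can give), which argues against independent chance placement for this window. A gained or lost copy of the whole end from 120 Mb on is argued against by its median difference from WT. That median was at most 0.091 in size over the 3 libraries labelled AICDA KO. The window from 130 to 140 Mb alone had a median log2 fold change of -0.232, and a copy change of part of it was not tested. Reads lost to strain variants in only one genotype would move genes one way, and 54.8% of the large changes from 120 Mb on went in the more frequent direction. This share was not taken for the window from 130 to 140 Mb alone, where the median was lower, so it does not decide the question there. A candidate explanation that stays open, as a hypothesis, is DNA of the strain of the targeted embryonic stem cells carried along with the allele, acting on the expression of nearby genes, which was not tested.

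The lower level of distal X genes in AICDA KO replicate 3 was not matched on its autosomes, where the largest step along a chromosome was 0.197 on the log2 scale, which argues against depth or scaling. It was not made by a few genes, since 99.1% of the 211 genes were lower. Loss or silencing of 1 of 2 copies, as a hypothesis, would give -1, and the median was -0.928 from the other libraries labelled AICDA KO but -0.695 from WT, so it stays open, as the number of X copies in the libraries is not given. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had reads in every library, at only 0.8 to 3.1 CPM. These low levels do not give the number of X copies. Higher dosage of distal X genes than in WT was also set against the lower ERK feedback genes of this library. Its distal X median of -0.695 was known before this comparison was written, and its ERK list mean was -0.60. Higher distal dosage is therefore argued against for this library alone. In replicates 1 and 2 the distal X medians were 0.20 and 0.18 and the ERK list means -0.50 and -0.65, so the question stays open there.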
